A study of Mus musculus with 6 samples.

How the data were processed

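Gene expression was measured on arrays in mouse embryonic stem cells that carry a green fluorescent protein (GFP) reporter knocked into Nkx2-1, the gene of a homeodomain transcription factor of the lung, thyroid and ventral forebrain. The cells, of the W4/129S6 background, were differentiated for 14 days and sorted. The series holds 3 samples of GFP-positive cells (Nkx2-1 high) and 3 of GFP-negative cells (Nkx2-1 low), described as biological replicates in the labels' protocols. Total RNA was amplified with the WT-Ovation Pico system and labelled with biotin by the Affymetrix protocol, per the labels' protocols. Such amplification can change the relative signal of transcripts, and no step here removes that effect.

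The values are the log2 expression values that the authors deposited. RMA is named in the submitters' processing notes. It subtracts background, equalises the distribution of the arrays and summarises probes into 1 value per transcript cluster. No source states the scale, and log2 was taken from the use of RMA and from the range of the values, with medians per array from 4.98 to 5.06. The version of RMA and the genome build are not given in the sources used here, so no coordinates are printed. Scanner files and detection calls were not used here. Scan dates and slides are not given in the sources used here, so array batches were not tested. The number of arrays limits the precision.

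The table held 29011 rows. Of these, 21789 had 1 gene symbol in GEO's platform annotation, 1621 had several and 5601 had none there. All but 91 of the single-symbol rows matched the RefSeq table of GRCm38.p6 through their Entrez gene ID, and 0 symbols needed updating. Rows with several symbols or none were left out. For the 999 genes with more than 1 row, the row with the highest mean over the 6 samples was used, which gave 19938 genes. A background level was set at the 95th percentile of the 1210 rows of olfactory and vomeronasal receptors, a log2 value of 4.30. A gene with both group means at or under this level is called not above background and is given no fold. Where only 1 group lay above it, the fold was taken against the level itself and is written as "at least". In all, 32.8% of the genes were not above background in either group.

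The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on all 6 samples, group as the only term), with Benjamini-Hochberg adjustment over the 19938 genes and a threshold of 0.05. Adjusted p-values of genes are from limma throughout. "Rose" and "fell" mean higher and lower in Nkx2-1 high at that threshold. Log2 differences are Nkx2-1 high minus Nkx2-1 low, with ± the standard error (SE) from limma. The design, the rule for named genes and 40 gene lists with 727 entries were fixed before the data were examined. Of the entries, 678 were measured, 15 lay on rows shared by several genes and 34 were not used here. Lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the 40 lists, and again with an estimated correlation and with fry. Nkx2-1 was in no list, because the cells were sorted on it. Tested on simulated data for this comparison over 19938 genes, the fit recovered 77.6% of the genes changed by 0.5 on the log2 scale and 100% of those changed by 1 or by 2. It made 15 false calls, and 0 calls when no gene was changed. The simulated noise was normal and independent between genes and samples, with no correlation between genes and no shared replicate effect. Performance on the real data can therefore be worse.

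The genes named are Nkx2-1, the 12 largest rises and 12 largest falls among called genes whose groups did not overlap (without predicted models, small RNAs and chemosensory receptors), up to 4 called members of each list with the largest change, or 2 members where none was called, and a set of key genes. Other genes are named where a count is spelled out or a member is singled out, and these were chosen after their values were seen.

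The alternatives were median-centred arrays, cyclic loess, only genes above background, only the genes brighter than the median gene, a mean-variance trend with robust eBayes, array weights, a replicate block, the mean over the rows of a gene, all rows in 1 fit, a threshold of 0.01, limma treat, a test per gene without eBayes, leaving out each sample in turn, and leaving out both samples numbered 3, which was chosen after the data were seen. The range of a list's adjusted p is over those of these alternatives that test lists with camera's preset correlation, and leaves out fry and the estimated correlation. Between replicates of a group, the median absolute log2 difference over genes ran from 0.0968 to 0.133, and no sample was a copy of another. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.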

Results

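Expression of 19938 genes was measured in 3 Nkx2-1 high and 3 Nkx2-1 low samples, sorted after 14 days of differentiation. The comparison asks how GFP-positive cells, sought as lung and thyroid progenitors, differed from the GFP-negative cells. Across genes, samples of a group correlated at Pearson r from 0.994 to 0.996 and samples of different groups at 0.989 to 0.991, and genes are not independent replicates. The first principal component, with 51.3% of the variance, separated the groups. On the second, with 19.7%, the samples numbered 3 of both groups lay on the opposite side from those numbered 1.

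Nkx2-1 itself was 5.25-fold higher in Nkx2-1 high. Its log2 expression was 7.72 ± 0.08 (SD, n = 3) in Nkx2-1 high and 5.33 ± 0.09 (SD, n = 3) in Nkx2-1 low, a difference of 2.39 ± 0.08 (SE, limma adjusted p = 3.03e-06). All 3 Nkx2-1 high samples lay above all 3 Nkx2-1 low samples, and an exact two-sided permutation test gave p = 0.1, the smallest that 3 samples against 3 allow. The mean in Nkx2-1 low was also above the background level of 4.30.

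In all, 1196 genes differed between the fractions, of which 579 rose and 617 fell. At least 2-fold changes were seen for 158 genes, 89 higher and 69 lower. Adgrg2, an adhesion G protein-coupled receptor gene, rose by 2.52 ± 0.14 on the log2 scale (5.72-fold). The growth factor gene Igf1 rose by 2.18 ± 0.16 (4.54-fold), Edil3, which encodes a secreted matrix protein, by 2.05 ± 0.15, and the receptor phosphatase gene Ptpro by 1.93 ± 0.12. Plcl1 (2.29 ± 0.11), Greb1 (1.92 ± 0.09), Mtmr7 (1.91 ± 0.10), the cation channel gene Trpc5 (1.87 ± 0.17) and Fosb (1.86 ± 0.20) rose as well. Galnt13 and Alox12 were above background only in Nkx2-1 high, at least 4.01-fold and at least 3.27-fold higher.

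The largest falls included genes of transcription factors, matrix proteins and receptors. The developmental gene Mab21l1 was 6.62-fold lower in Nkx2-1 high (log2 difference -2.73 ± 0.21), Tnn, a tenascin gene, 6.29-fold lower (-2.65 ± 0.11), and the LIM-homeodomain gene Lhx8 5.8-fold lower (-2.54 ± 0.10). The orphan receptor gene Gpr50 (-2.50 ± 0.26), Postn, which encodes the matrix protein periostin (-2.34 ± 0.16), Tfap2c (-2.11 ± 0.21), the craniofacial homeobox gene Alx1 (-2.10 ± 0.15) and the activin subunit gene Inhba (-2.09 ± 0.17) fell. So did Pdgfra, a growth factor receptor gene of mesenchyme (3.99-fold), Crabp1, which encodes a retinoic acid-binding protein (-1.92 ± 0.12), and Prrx1, a homeobox gene of limb and facial mesenchyme (-1.90 ± 0.14). Ptprz1 was above background only in Nkx2-1 low, at least 4.53-fold lower in Nkx2-1 high. The groups did not overlap for any of the 1196 genes, nor for 24.67% of all genes, where chance gives 10%. With 3 samples against 3, a call all but requires such separation, so it adds no support to the calls. Genes are correlated, and no spread was computed around the 10%. The number of changed genes was 772 without Nkx2-1 high replicate 1, 624 without Nkx2-1 high replicate 2, 765 without Nkx2-1 low replicate 1 and 709 without Nkx2-1 low replicate 2. A test per gene without eBayes called 89.

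**Figure D1:**
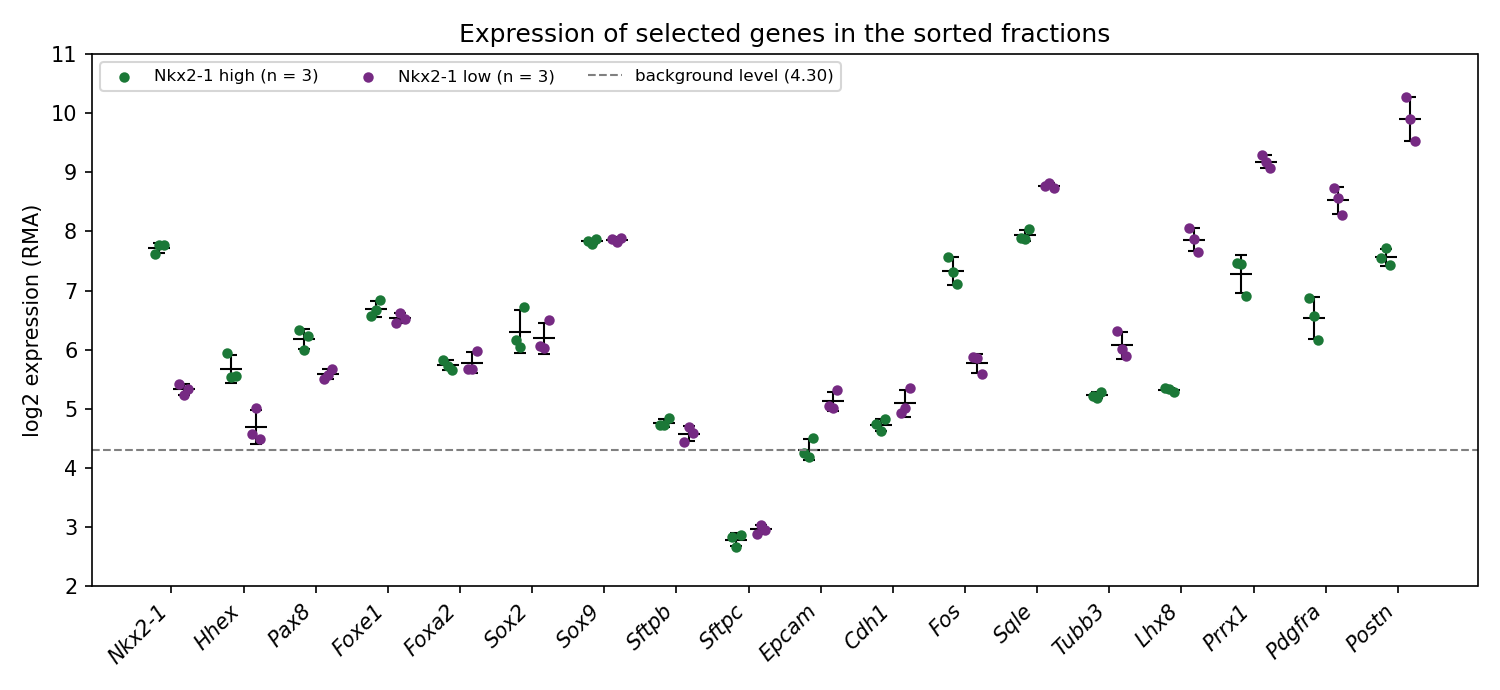
Log2 expression (RMA, vertical axis) of 18 genes in the 3 Nkx2-1 high samples (green) and the 3 Nkx2-1 low samples (purple). Points are samples, black bars are the mean ± SD, and the dashed line is the background level of 4.30; Nkx2-1, Hhex, Pax8 and Fos lie higher in Nkx2-1 high, Epcam, Sqle, Tubb3, Lhx8, Prrx1, Pdgfra and Postn lie lower, and the groups overlap for Foxa2, Sox2 and Sox9.

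Hhex and Pax8, transcription factor genes of the thyroid primordium that other tissues also express, rose. Hhex was 1.98-fold higher (log2 difference 0.98 ± 0.15, adjusted p = 0.00538) and Pax8 1.51-fold higher (0.60 ± 0.10, adjusted p = 0.00720). Foxe1, another early thyroid factor gene, stood at 6.70 ± 0.14 (SD, n = 3) in Nkx2-1 high and 6.53 ± 0.08 (SD, n = 3) in Nkx2-1 low (limma adjusted p = 0.399). Thyroglobulin (Tg) and the thyrotropin receptor gene Tshr were not above background. Of 16 measured thyroid genes, 8 were above background in at least 1 group. Of the 16, 2 rose and 0 fell, and adjusted over the list alone 3 rose. As a list they were higher in Nkx2-1 high (median log2 difference 0.16, camera adjusted p = 0.00103). The adjusted p was 0.164 with an estimated correlation.

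Genes of the lung epithelium did not shift as lists. Of 19 early lung genes 1 rose and 2 fell, and adjusted over the list alone 2 rose and 2 fell (camera adjusted p = 0.986). Bmp4, a signal of the distal lung bud, was 1.95-fold higher (0.97 ± 0.09). The 2 that fell were Id2 (-0.46 ± 0.10, lost in 4 of the 6 fits without 1 sample, adjusted p up to 0.0868) and Fgfr2 (-0.61 ± 0.15, lost in 5 of the 6 fits without 1 sample, adjusted p up to 0.147). Differences that did not pass were -0.03 ± 0.07 for Sox9, 0.07 ± 0.09 for Foxp2, 0.06 ± 0.11 for Irx1, -0.02 ± 0.09 for Gata6 and -0.35 ± 0.18 for Shh. Of 21 genes of lung maturation, 8 were above background in at least 1 group and 1 rose, the surfactant gene Sftpa1 (0.49 ± 0.09, list camera adjusted p = 0.659). Sftpb stood at 4.76 ± 0.07 (SD, n = 3) in Nkx2-1 high and 4.58 ± 0.13 (SD, n = 3) in Nkx2-1 low (limma adjusted p = 0.318). Sftpc, Scgb1a1 and Scgb3a2, genes of surfactant and secretory cells, were not above background.

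Of 17 definitive endoderm genes, 0 rose and 0 fell by limma, with 1 higher and 3 lower at an unadjusted p under 0.05 (camera adjusted p = 0.593). Foxa2, a pioneer factor gene of endoderm, stood at 5.74 ± 0.09 (SD, n = 3) in Nkx2-1 high and 5.78 ± 0.18 (SD, n = 3) in Nkx2-1 low (limma adjusted p = 0.884), and the 95% interval of its difference ran from -0.27 to 0.19. Foxa1 differed by -0.41 ± 0.24 and Cldn6 by -0.40 ± 0.15, neither past the test, and Sox17 was not above background. Epithelial genes moved both ways. Of 37 genes of junctions and keratins 2 rose and 2 fell (mean -0.07, camera adjusted p = 0.237). With only the genes brighter than the median gene the list was called in the other direction (mean 0.29, adjusted p = 0.0197), in a range of 0.0197 to 0.610 over the alternatives with the preset correlation. The adhesion gene Epcam was 1.76-fold lower (-0.81 ± 0.11), with a mean of 4.31 in Nkx2-1 high, next to the background level, and Tmem30b was at least 1.56-fold lower (lost in 1 of the 6 fits without 1 sample, adjusted p up to 0.0528). The P-cadherin gene Cdh3 rose (0.80 ± 0.13), as did Jup (0.58 ± 0.12, lost in 5 of the 6 fits without 1 sample, adjusted p up to 0.0813). The E-cadherin gene Cdh1 differed by -0.36 ± 0.12 (adjusted p = 0.114), Cdh2 by 0.07 ± 0.10 and the vimentin gene Vim by 0.16 ± 0.08 (adjusted p = 0.315). Among 16 genes of basal and stratified epithelium 1 rose, the integrin gene Itga6 (1.00 ± 0.09), and Trp63 differed by -0.05 ± 0.08 (list camera adjusted p = 0.554).

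Single genes of the pharyngeal foregut list moved in opposite directions. The LIM-homeodomain gene Isl1 was 2.51-fold higher (1.33 ± 0.15), and Pax9, a gene of the pharyngeal pouches that facial mesenchyme also expresses, was 2.42-fold lower (-1.28 ± 0.13). Tbx1 fell too (-0.54 ± 0.12, lost in 4 of the 6 fits without 1 sample, adjusted p up to 0.110), and Sox2 differed by 0.11 ± 0.18 (adjusted p = 0.808). Of 13 members 1 rose and 2 fell (camera adjusted p = 0.659). Of 14 stomach genes Barx1 fell (-0.63 ± 0.10, list adjusted p = 0.986). Of 21 liver genes Trf (-0.49 ± 0.11, lost in 5 of the 6 fits without 1 sample, adjusted p up to 0.116) and Dlk1 (-0.36 ± 0.09, lost in 5 of the 6 fits without 1 sample, adjusted p up to 0.166) fell (list adjusted p = 0.959), Hnf4a differed by -0.04 ± 0.14, and Alb and Afp were not above background. Of 15 pancreas genes Nkx6-1 rose (0.87 ± 0.10) and Neurod1 fell, at levels not above background (lost in 3 of the 6 fits without 1 sample, adjusted p up to 0.0707), as was Pdx1 (list adjusted p = 0.395). Of 17 intestine genes Lgr5, a Wnt target and stem cell gene, fell (-1.16 ± 0.18, list adjusted p = 0.986), and Cdx2 was not above background. Of 21 pluripotency genes Klf4 rose (0.65 ± 0.09, list adjusted p = 0.285), and neither Pou5f1 nor Nanog was above background.

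Neuronal genes were lower in Nkx2-1 high. Of 17 measured members 8 fell and 0 rose, and adjusted over the list alone 13 fell (median -0.54, camera adjusted p = 3.56e-11). The adjusted p was 0.167 with an estimated correlation. Ina, an intermediate filament gene of neurons, was 2.99-fold lower (-1.58 ± 0.14), the growth cone gene Gap43 1.85-fold lower (-0.89 ± 0.11) and Tubb3, which encodes neuronal tubulin, 1.79-fold lower (-0.84 ± 0.11). Dcx and Stmn2 were above background only in Nkx2-1 low, at least 2.24-fold and at least 1.75-fold lower. Of the 8 that fell, Elavl4 lost the call in 4 of the 6 fits without 1 sample (adjusted p up to 0.106), and the others kept it. Of 16 ventral forebrain genes 6 fell and 0 rose, and adjusted over the list alone 0 rose and 6 fell (median -0.10, mean -0.43, camera adjusted p = 0.00694, and adjusted p = 0.167 with an estimated correlation). Besides Lhx8 they were Lhx6 (-1.52 ± 0.14), Dlx5 (-0.93 ± 0.10), Dlx1 (-0.93 ± 0.21, lost in 3 of the 6 fits without 1 sample, adjusted p up to 0.108), Dlx2 (-0.72 ± 0.14, lost in 2 of the 6 fits without 1 sample, adjusted p up to 0.0599) and Gad2, at least 1.28-fold lower. Lhx6, Lhx8, Dlx1, Dlx2 and Dlx5 are also expressed in mesenchyme of the first pharyngeal arch. Of 10 neuroendocrine genes 2 fell (3 adjusted over the list alone), Grp, at least 1.19-fold lower, and Scg3, not above background (camera adjusted p = 0.000816, and adjusted p = 0.164 with an estimated correlation). With only genes above background the adjusted p of that list was 0.109, in a range of 0.000109 to 0.109 over the alternatives with the preset correlation. Of 16 progenitor genes of the forebrain and neural tube, Fabp7 (-0.60 ± 0.14, lost in 4 of the 6 fits without 1 sample, adjusted p up to 0.147) and Nes (-0.41 ± 0.10, lost in 5 of the 6 fits without 1 sample, adjusted p up to 0.169) fell and Rax rose, at least 1.32-fold (lost in 2 of the 6 fits without 1 sample, adjusted p up to 0.0630), with camera adjusted p = 0.986 for the list. Otx2 had the largest difference of that list (1.04 ± 0.28) but did not pass (limma adjusted p = 0.0665). Sox1 differed by -0.01 ± 0.10, and Pax6 was not above background.

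Genes of mesenchyme and neural crest were among the largest falls. Of 31 mesenchyme and matrix genes 11 fell and 3 rose, and adjusted over the list alone 5 rose and 13 fell (median -0.04, mean -0.38, camera adjusted p = 0.00333, and adjusted p = 0.646 with an estimated correlation). Besides Postn, Pdgfra and Prrx1, the collagen genes Col1a2 (-1.50 ± 0.08, 2.82-fold) and Col1a1 (-0.90 ± 0.09, 1.86-fold) fell. Meox1 (1.26 ± 0.24, lost in 1 of the 6 fits without 1 sample, adjusted p up to 0.0601), Col5a2 (0.44 ± 0.09, lost in 5 of the 6 fits without 1 sample, adjusted p up to 0.0637) and Zeb2 (0.44 ± 0.08, lost in 3 of the 6 fits without 1 sample, adjusted p up to 0.0705) rose. In Nkx2-1 high, Col1a1 (8.99), Col1a2 (8.62) and Postn (7.56) stayed well above background. Of the 17 members that did not pass, Pdgfrb stood at 9.68 in Nkx2-1 high and 9.64 in Nkx2-1 low. Fn1 stood at 10.78 and 10.29, and Lum at 5.69 and 6.44. The falls thus do not show that Nkx2-1 high lacked mesenchymal expression. Of the 11 that fell, Snai1 and Foxf1 each lost the call in 5 of the 6 fits without 1 sample (adjusted p up to 0.1445 and 0.1211). The list's adjusted p was 0.0564 without Nkx2-1 high replicate 3 and 0.0648 without Nkx2-1 low replicate 1. It ran from 6.44e-05 to 0.0648 over the alternatives with the preset correlation. Of 11 neural crest genes 4 fell and 0 rose, and adjusted over the list alone 0 rose and 6 fell (median -0.26, camera adjusted p = 5.15e-05, and adjusted p = 0.117 with an estimated correlation). They were Crabp1, the homeobox gene Msx1 (-1.59 ± 0.11, 3.02-fold), Tfap2b, at least 1.35-fold lower, and Snai2 (-0.65 ± 0.15, lost in 5 of the 6 fits without 1 sample, adjusted p up to 0.122). The crest genes Sox10 (0.16 ± 0.08) and Foxd3 (0.03 ± 0.10) did not pass.

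Among other cell types, 3 of 18 endothelial genes rose and 0 fell (median 0.03, mean 0.20). The list missed the threshold with camera (adjusted p = 0.0562) and passed with fry (adjusted p = 0.0162). The receptor gene Flt4 was 2.14-fold higher (1.10 ± 0.08), Tek at least 1.73-fold higher, and Eng rose by 0.88 ± 0.21 (0.88 ± 0.21, lost in 4 of the 6 fits without 1 sample, adjusted p up to 0.122). Pecam1, above background only in Nkx2-1 high, was at least 1.095-fold higher there but did not pass (limma adjusted p = 0.0985), and Cdh5 was not above background. The endothelial list passed without Nkx2-1 high replicate 3 (adjusted p = 0.0188) and without Nkx2-1 low replicate 2 (adjusted p = 0.0457), in a range of 0.00485 to 0.115 over the alternatives with the preset correlation. Of 20 blood genes 0 rose and 0 fell by limma, with 1 higher and 0 lower at an unadjusted p under 0.05 (camera adjusted p = 0.290, fry adjusted p = 0.00994), and Ptprc was not above background. Of 20 muscle and heart genes Ryr2 (0.51 ± 0.08) and Hand1 (0.34 ± 0.08, lost in 6 of the 6 fits without 1 sample, adjusted p up to 0.148) rose (list adjusted p = 0.299). In the list of kidney and intermediate mesoderm, with 13 genes, Gata3 (0.78 ± 0.12) and Wt1 (0.48 ± 0.08) rose and Hoxd11 (-0.60 ± 0.12, lost in 5 of the 6 fits without 1 sample, adjusted p up to 0.0771), Osr1 (lost in 2 of the 6 fits without 1 sample, adjusted p up to 0.0708) and Six2 (-0.40 ± 0.07, lost in 1 of the 6 fits without 1 sample, adjusted p up to 0.0586) fell (list adjusted p = 0.813). Among 15 genes of extra-embryonic endoderm the laminin gene Lamc1 was 2.18-fold higher (1.13 ± 0.08), and Pth1r (-0.69 ± 0.10) and the collagen genes Col4a1 (-0.64 ± 0.08) and Col4a2 (-0.59 ± 0.08) fell (list adjusted p = 0.308). Of 8 trophoblast genes Hand1 rose and Tfap2c fell (list adjusted p = 0.986), and of 18 genes of motile cilia 0 rose and 0 fell by limma with 3 higher and 0 lower at an unadjusted p under 0.05 (list adjusted p = 0.185).

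**Figure D2:**
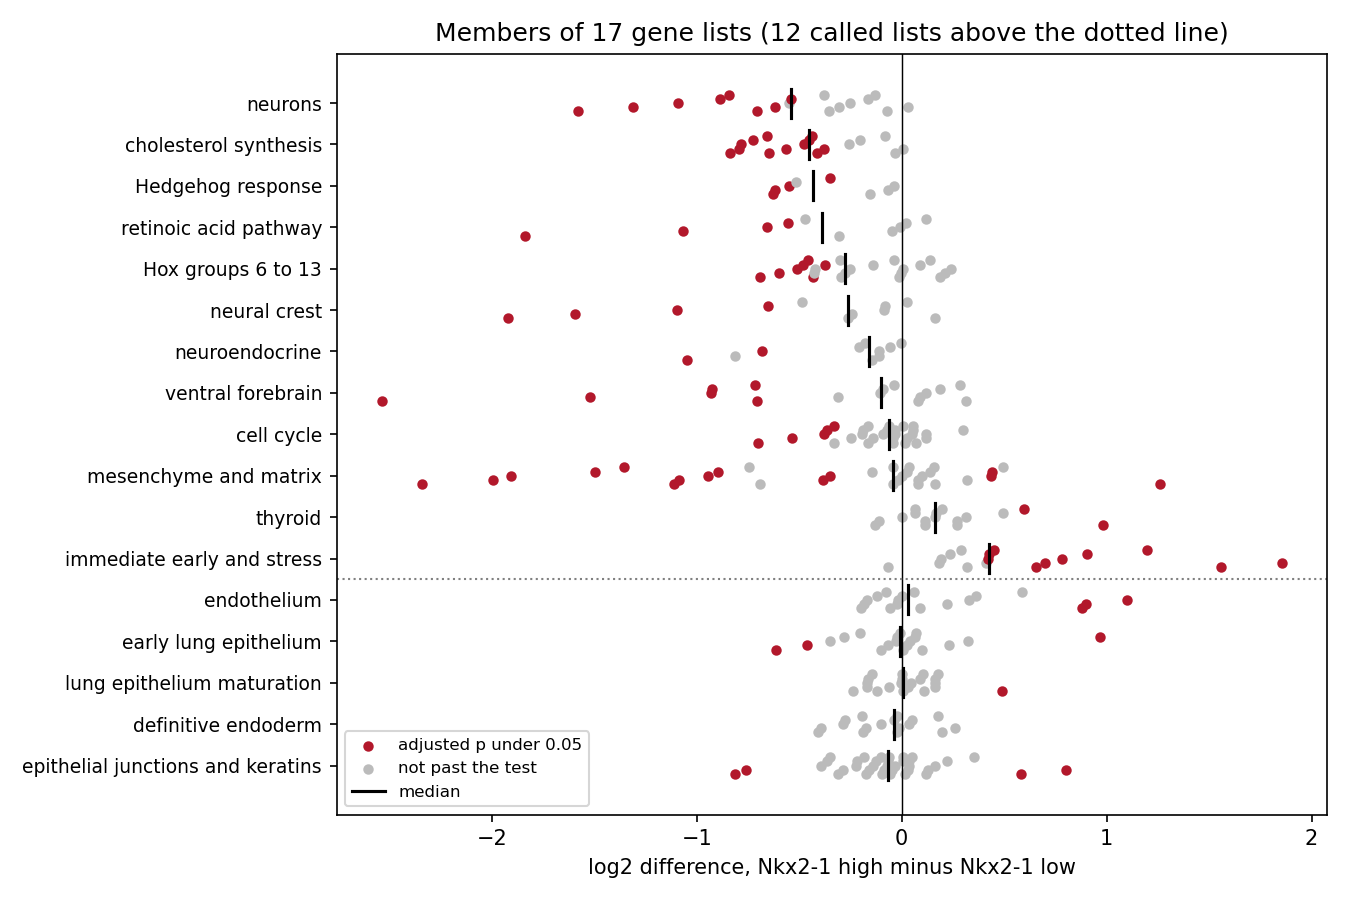
Log2 difference between Nkx2-1 high and Nkx2-1 low (horizontal axis) for the measured members of 17 gene lists, the 12 called by camera above the dotted line and the others below it. Each point is a gene, red where its limma adjusted p was under 0.05 and grey otherwise, and black bars are medians, which reach from -0.54 for neurons to 0.43 for immediate early and stress genes.

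Immediate early genes, which switch on within minutes of a stimulus, were higher in Nkx2-1 high. Of 17 measured members of the immediate early and stress list 10 rose and 0 fell, and adjusted over the list alone 13 rose (median 0.43, camera adjusted p = 3.23e-14). The adjusted p was 0.0388 with an estimated correlation. Fosb was 3.62-fold higher, Fos 2.95-fold higher (1.56 ± 0.13), the phosphatase gene Dusp1 2.3-fold higher (1.20 ± 0.08) and the anti-proliferative gene Btg2 1.87-fold higher (0.91 ± 0.09). Of the 10 that rose, Gadd45b lost the call in 5 of the 6 fits without 1 sample (adjusted p up to 0.102). Junb, Jund and Zfp36 lost it in 3 each (adjusted p up to 0.0798, 0.0691 and 0.0850), and the others kept it. Among members that did not pass, the heat-shock gene Hspa1a differed by 0.19 ± 0.11 (adjusted p = 0.410), and Egr1 differed by 0.29 ± 0.10 (adjusted p = 0.137).

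Cholesterol synthesis genes were lower in Nkx2-1 high. Of 17 measured members 12 fell and 0 rose, and adjusted over the list alone 14 fell (median -0.45, camera adjusted p = 3.21e-13). The adjusted p was 0.0959 with an estimated correlation. Sqle was 1.79-fold lower (-0.84 ± 0.08), Hmgcs1 1.73-fold lower (-0.79 ± 0.10), Msmo1 1.72-fold lower (-0.78 ± 0.11) and Cyp51 1.65-fold lower (-0.72 ± 0.10). Of the 12 that fell, Fdft1 lost the call in 6 of the 6 fits without 1 sample (adjusted p up to 0.115). Dhcr7 lost it in 4 (up to 0.0778) and Mvd in 2 (up to 0.0694), and the others kept it. Of 29 cell cycle genes 5 fell and 0 rose, and adjusted over the list alone 0 rose and 5 fell (camera adjusted p = 0.0229, and adjusted p = 0.646 with an estimated correlation). Those that fell were Ccne1 (-0.70 ± 0.08), Rrm2 (-0.54 ± 0.07), Pcna (-0.33 ± 0.08, lost in 6 of the 6 fits without 1 sample, adjusted p up to 0.101), Mcm6 (-0.38 ± 0.09, lost in 6 of the 6 fits without 1 sample, adjusted p up to 0.128) and Mcm2 (-0.36 ± 0.09, lost in 5 of the 6 fits without 1 sample, adjusted p up to 0.121). Mki67, a marker of cycling cells, differed by -0.03 ± 0.07. The list's adjusted p was 0.258 without Nkx2-1 high replicate 3 and 0.143 without Nkx2-1 low replicate 1, in a range of 0.00215 to 0.258 over the alternatives with the preset correlation.

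Retinoic acid and Hedgehog genes were lower in Nkx2-1 high. Of 10 retinoic acid pathway genes 4 fell and 0 rose, and adjusted over the list alone 0 rose and 6 fell (median -0.39, camera adjusted p = 0.000763, and adjusted p = 0.193 with an estimated correlation). Crabp2, which encodes a retinoic acid-binding protein, was 3.57-fold lower (-1.84 ± 0.09), and the retinol transporter gene Stra6 (-0.66 ± 0.10) and Dhrs3 (-0.56 ± 0.10) fell. So did Aldh1a2, the gene of a retinoic acid-making enzyme (-1.07 ± 0.25, lost in 5 of the 6 fits without 1 sample, adjusted p up to 0.121). Of 8 Hedgehog response genes 4 fell and 0 rose, and adjusted over the list alone 0 rose and 5 fell (median -0.43, camera adjusted p = 0.000712, and adjusted p = 0.212 with an estimated correlation). Gli1, a direct Hedgehog target, fell (-0.63 ± 0.10), as did Foxf2 (-0.62 ± 0.15, lost in 5 of the 6 fits without 1 sample, adjusted p up to 0.133), Foxf1 (-0.35 ± 0.08, lost in 5 of the 6 fits without 1 sample, adjusted p up to 0.121) and Osr1 (lost in 2 of the 6 fits without 1 sample, adjusted p up to 0.0708), which are also genes of mesenchyme. A dimmer second row of Foxf1, under the background level, differed by 0.09. Of 23 Hox genes of groups 6 to 13, 7 fell and 0 rose, and adjusted over the list alone 2 rose and 11 fell (median -0.28, camera adjusted p = 0.00230, and adjusted p = 0.212 with an estimated correlation). Above background in both groups were Hoxa9 (-0.46 ± 0.10, lost in 5 of the 6 fits without 1 sample, adjusted p up to 0.0917), Hoxd9 (-0.48 ± 0.11, lost in 4 of the 6 fits without 1 sample, adjusted p up to 0.0958), Hoxd10 (-0.69 ± 0.16, lost in 4 of the 6 fits without 1 sample, adjusted p up to 0.0951) and Hoxd11 (-0.60 ± 0.12, lost in 5 of the 6 fits without 1 sample, adjusted p up to 0.0771), and with only genes above background the list's adjusted p was 0.13, in a range of 0.000207 to 0.13 over the alternatives with the preset correlation. Of 14 Hox genes of groups 1 to 5, Hoxa5 fell, at levels not above background (lost in 5 of the 6 fits without 1 sample, adjusted p up to 0.108, list adjusted p = 0.737).

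The remaining lists were not called by camera. Of 13 Wnt feedback genes Dkk1 (-1.21 ± 0.16, 2.31-fold), Lgr5 and Lef1 (-0.59 ± 0.08) fell and Sp5 rose (0.50 ± 0.10, lost in 3 of the 6 fits without 1 sample, adjusted p up to 0.0691), with list adjusted p = 0.0885, and 0.00535 without Nkx2-1 high replicate 3, in a range of 0.00181 to 0.245 over the alternatives with the preset correlation. Of 12 BMP feedback genes Grem1 (0.66 ± 0.12) and Bambi (0.36 ± 0.09, lost in 6 of the 6 fits without 1 sample, adjusted p up to 0.136) rose and Msx1 and Id2 (-0.46 ± 0.10, lost in 4 of the 6 fits without 1 sample, adjusted p up to 0.0868) fell (list adjusted p = 0.140). Of 13 FGF feedback genes Etv1 rose (0.67 ± 0.11, list adjusted p = 0.157). Among 14 Notch pathway genes Hey2 was 2.34-fold higher (1.23 ± 0.14), and Notch1 (-0.56 ± 0.09) and Hey1 (-0.43 ± 0.09, lost in 3 of the 6 fits without 1 sample, adjusted p up to 0.0824) fell (list adjusted p = 0.986). Of 19 genes of hypoxia and glycolysis Car9 fell, at levels not above background (list adjusted p = 0.0885). That list's adjusted p was 2.38e-06 without Nkx2-1 high replicate 3 and 0.0280 without Nkx2-1 low replicate 2, with lower values in Nkx2-1 high, in a range of 2.38e-06 to 0.582 over the alternatives with the preset correlation. Of 12 genes of antigen presentation and interferon Irf1 rose (0.36 ± 0.08, lost in 5 of the 6 fits without 1 sample, adjusted p up to 0.130, list adjusted p = 0.237), and a second row of Irf1 differed by 0.07. Of 16 imprinted genes Grb10 rose (0.57 ± 0.08) and Peg10 (-0.82 ± 0.09) and Dlk1 (-0.36 ± 0.09, lost in 5 of the 6 fits without 1 sample, adjusted p up to 0.166) fell (list adjusted p = 0.675). Of 21 ribosomal protein genes 0 rose and 0 fell by limma, with 2 higher and 0 lower at an unadjusted p under 0.05 (list adjusted p = 0.743).

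Camera with its preset correlation called 12 of the 40 lists, 2 higher and 10 lower in Nkx2-1 high. With an estimated correlation 1 list was called, the immediate early and stress genes. Fry called 11 lists, of which camera also called 9, and it did not call the mesenchyme, Hedgehog or cell cycle lists. The 2 that fry called and camera did not were the blood (fry adjusted p = 0.00994) and endothelial (fry adjusted p = 0.0162) lists, both higher in Nkx2-1 high. Of the 20 blood genes only 8 were above background in at least 1 group, and the median log2 difference of the list was 0.04. The endothelial list had a median of 0.03 and a mean of 0.20, with 7 members higher and 2 lower at an unadjusted p under 0.05. The median, mean and camera direction differed in sign for the stomach, forebrain progenitor, trophoblast and Notch lists. Adjusted over the list alone, 2 rose and 2 fell of the pharyngeal foregut list, 0 rose and 3 fell of the liver list, 3 rose and 3 fell of the forebrain progenitor list, 5 rose and 0 fell of the endothelial list, 4 rose and 4 fell of the kidney list, 1 rose and 4 fell of the extra-embryonic endoderm list, 2 rose and 4 fell of the junction and keratin list, 2 rose and 5 fell of the Wnt list, 6 rose and 2 fell of the BMP list and 1 rose and 3 fell of the Notch list. For the lists whose counts so adjusted are not given, they equalled those over all genes. Over all genes tested, 3790 had an unadjusted p under 0.05.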

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

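Nkx2-1 kept its direction and its call under every alternative run for it, with log2 differences from 2.34 to 2.44. The number of changed genes (1196) was 507 at adjusted p under 0.01 and 109 with limma treat at a log2 difference of 0.5, both stricter by construction. It was 89 in a test per gene without eBayes. That test lacks the 5.54 prior degrees of freedom that eBayes takes from all genes (9.54 in total). The larger count thus rests on sharing variance across genes. Without 1 sample it ran from 624 to 1086, in fits with fewer samples, and 610 of the 624 were among the 1196. Without both samples numbered 3, an alternative chosen after the data were seen, it was 877, of which 739 were shared. Under the other normalizations, filters, variance models, weights and choices of rows it ran from 1106 to 1681. The number of changed genes of at least 2-fold (158) ran from 129 to 183. The number of gene lists (12) ran from 10 to 15 with the preset correlation, was 11 with fry and was 1 with an estimated correlation. With the replicate block 1470 genes were called, 1145 of them shared, and 15 lists, which added those of endothelium (adjusted p = 0.0319), Wnt feedback (adjusted p = 0.0226) and hypoxia and glycolysis (adjusted p = 0.0226) to the 12. Whether the numbers pair the samples is not settled. Same-numbered samples deviated from their group means with r = 0.181, -0.004 and 0.277 across genes. Over genes above background, r was 0.275, 0.017 and 0.411. Nkx2-1 high replicate 1 with Nkx2-1 low replicate 3 gave -0.192 across genes, and Nkx2-1 high replicate 3 with Nkx2-1 low replicate 1 gave -0.269. Not every sample correlated best with its own number, so a shared culture or day can be neither shown nor excluded. No named gene changed direction in a fit that called it. Of the lists, that of epithelial junctions and keratins changed direction, from a mean of -0.07 to 0.29 with only the genes brighter than the median gene (adjusted p = 0.0197), a setting that leaves out its dimmer members. Of the 111 named genes that were called, 82 kept the call in all 6 fits without 1 sample and 29 lost it in at least 1. Signal over background limits the dim genes, since 32.8% of genes were not above background in either group.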

Other observations

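The extra gene lists, the gene families and the genes next to Nkx2-1 were chosen after the main results were seen. The tests on the neighbours and on the immediate early genes without 1 sample were chosen after the values they measure were seen. Of 10 genes linked to ventral forebrain interneurons 4 rose and 0 fell: Sst, the somatostatin gene (1.11 ± 0.16), Sox6 (0.88 ± 0.08), Maf (0.88 ± 0.08) and Erbb4 (0.63 ± 0.11). Of 15 genes of fatty acid synthesis and related lipid metabolism 4 fell and 0 rose: Elovl6 (-0.59 ± 0.07), Acaca (-0.54 ± 0.08), Acss2 (-0.51 ± 0.11, lost in 4 of the 6 fits without 1 sample, adjusted p up to 0.109) and Scd1 (-0.31 ± 0.08, lost in 5 of the 6 fits without 1 sample, adjusted p up to 0.156). Their mean log2 difference was -0.189 (95% interval -0.286 to -0.0923, p = 0.0812 with an estimated correlation), so a mean fall of over 0.1 was not settled. Among 129 families of genes that share a symbol root, 4 passed with camera's preset correlation and 0 with an estimated one (2 at an unadjusted p under 0.05). They were the Snord (31 genes, 5 fell), Pcdhb (22 genes, 2 fell) and Snora (20 genes, 2 rose and 4 fell) families, lower in Nkx2-1 high, and the Klf family (17 genes, 4 rose), higher.

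The 6 samples make 10 splits into 3 and 3, too few for a share under 0.05. Only 1 split, the real one, gave as many changed genes (1196, highest other 0), changed genes of at least 2-fold (158, highest other 0) and lists (12, highest other 11). Every other split mixes the fractions, so the difference between them widens the spread within its groups. The 0 counts of genes therefore do not measure chance. With 11 lists in a mixed split, the number of lists called at the preset correlation does not by itself set the real split apart. The split with 11 lists set Nkx2-1 high replicates 1 and 2 and Nkx2-1 low replicate 1 against the rest. These samples are those with positive values on the second principal component.

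Immediate early genes were higher in Nkx2-1 high. A general heat-shock response to handling is argued against: 15 heat-shock chaperones had a mean log2 difference of -0.133 (95% interval -0.281 to 0.0147, p = 0.290 with an estimated correlation). A response in 1 Nkx2-1 high sample is argued against too, as the list's median stayed at 0.392 or more without any 1 sample, against 0.426 with all. The groups did not overlap for any called member, so this test adds little to the calls themselves. Whether the response is wider than the list stays open. A further 19 early response genes, some of them immediate early genes too, had a mean of 0.149 (95% interval 0.0707 to 0.228, p = 0.0421 with an estimated correlation). The immediate early genes Egr2 (0.06 ± 0.17), Arc (0.03 ± 0.08) and Egr3 (-0.26 ± 0.09) did not pass, nor did Myc (-0.22 ± 0.11). Of the 19, 3 rose and 0 fell: Socs3 (0.88 ± 0.14), Rhob (0.65 ± 0.08) and Ccn1 (0.78 ± 0.08). Signalling in these cells and a handling response that spares heat-shock genes may each account for the rise of the immediate early list, and neither was tested.

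Lhx6, Lhx8, Dlx1, Dlx2 and Dlx5, shared by ventral forebrain and facial mesenchyme, fell. Whether ventral forebrain interneurons lay among the Nkx2-1 low samples is not settled. The 10 interneuron genes had a mean log2 difference of 0.378 (95% interval 0.211 to 0.544, p = 0.0652 with an estimated correlation). That is not the fall such cells would give, but it rests on the 4 that rose. The other 6 ran from -0.11 to 0.31, with Slc32a1 at -0.02 ± 0.09, and Calb2 and Nxph1 were not above background. Other tissues express several of these genes. The GABA synthesis gene Gad2 fell, near the background level, and the brighter Gad1 differed by 0.08 ± 0.08 (limma adjusted p = 0.690). The mean of the 10 genes therefore cannot decide it. Neurons of other kinds stay open too. Whether first arch ectomesenchyme, which a sort on GFP would not remove from the negative cells, was a source is not settled either. The 8 genes linked to it had a mean of -0.267 (95% interval -0.395 to -0.139, p = 0.122 with an estimated correlation), a fall such cells would give. That mean rests on Alx4 (-1.19 ± 0.10), which other mesenchyme also expresses, and Shox2, which was not above background. The rest did not pass. Efnb1 stood at 7.44 in Nkx2-1 high and 7.45 in Nkx2-1 low (difference -0.01 ± 0.10), Osr2 at 6.45 and 6.18 (0.27 ± 0.14) and Pitx1 at 6.01 and 6.21 (-0.20 ± 0.13). Dlx3 differed by -0.17 ± 0.09, Dlx4 by -0.07 ± 0.08 and Nkx3-2 by -0.02 ± 0.11. This mean therefore cannot decide the source.

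Beside Nkx2-1, its neighbour Mbip rose (1.34 ± 0.08, 2.54-fold) and Pax9, 2 measured genes away on the other side, fell (-1.28 ± 0.13). Gene order is that of the RefSeq table of GRCm38.p6. Among the 10 nearest measured genes these 2 changed. As many changed genes were found in 13.3% of 19708 windows of 10 genes, so their number does not stand out.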
